A study of Mus musculus with 2 samples.

How the data were processed

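Chromatin immunoprecipitation with sequencing (ChIP-seq) for histone H3 monomethylated at lysine 4 (H3K4me1) was carried out on midbrain from mice at postnatal day 0 (P0). H3K4me1 is a histone mark found at enhancers and beside promoters. Per the labels, the series holds 2 biological replicates of this single group. Each was pooled tissue of both sexes from the strain named B6NTac;B6NCrl/Lap, with a size range of 300 to 500 bases. Replicate 1 came from 15 mice, and the number behind replicate 2 is not given in the sources used here. The labels name neither a second group nor a control among the samples, so no test between groups was possible, and a result is described within this tissue or set against random placement.

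The deposited files are peak lists in mouse assembly mm10, per the text records deposited beside them. The authors called peaks on each replicate alone and on both replicates pooled, each time against a control alignment, and deposited a further list named replicated peaks, derived from the other lists. The aligner, the peak caller, its thresholds and the rule for the replicated list are not given in the sources used here. For each peak the deposited lists give its start, end and highest point. They also give a display score, a fold value, which is the ratio of the highest point to the local background, and the −log10 p-value and −log10 q-value there. The deposited display score, whose making is not given in the sources used here, was not used. The fold, p and q are the authors' own values for each peak, and served only to describe, rank or filter peaks within a list. In both replicates' lists, the deposited fold and −log10 p were reproduced by a whole-number height n and a background b, with fold equal to (n + 1)/(b + 1) and p the Poisson probability of more than n reads. That held for 100% of peaks within 0.001 in −log10 p, and n and b are called the recovered height and background below. The read depth of the libraries is not recorded in the lists, so only the recovered heights and backgrounds bear on it.

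Coordinates are those of the lists. The reference was GRCm38, the assembly also called mm10, with the GENCODE M21 gene annotation. Chromosomes 1 to 19 and X entered the computations, which left out 1 peak of replicate 1 and 1 pooled peak on other scaffolds. The lists held 0 peaks on chromosome Y. A gene start is the 5′-most annotated base of a protein-coding gene, and 21728 such genes were used, 1 record per symbol. All intervals and tests were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots made with Matplotlib 3.10.9.

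Peaks of the replicates were compared by overlap of at least 1 base, against 100 random placements of the same peaks within their chromosome outside gaps in the assembly (permutation test, one-sided). The smallest p these placements can give is 0.0099. Bases of replicated peaks were assigned in order to promoters (1000 bases either side of a gene start), 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic sequence. Introns are the remaining bases of annotated genes of any type. The shares were set against 100 placements (two-sided permutation test, smallest p 0.0198) with Benjamini-Hochberg adjustment over the classes. The profile around gene starts was computed in steps of 100 bases out to 5000 bases. Gene coverage is the share of bases within 20000 of the gene start covered by replicated peaks. The median coverage of a list was compared with 10000 random lists of the same size and the same gene-length class (5 classes of equal size, two-sided permutation test, Benjamini-Hochberg over 24 lists). These were 21 lists of 320 entries in all for cell types, regions and pathways, and the Hox, olfactory receptor and vomeronasal receptor families by symbol. Random lists were drawn from all protein-coding genes of the class. The tested list's own members and the receptor genes, nearly all at 0%, stayed in that pool and can lower the medians of random lists. A median cannot fall below 0%, and random lists often had 0%. Only 2 of the 24 lists could therefore reach a raw p under 0.05 as lower, while by the mean over members, an alternative, all could. Where the text below says that a list could be lower, it means this raw p unless the adjustment is named. Broad domains are replicated peaks joined across gaps of up to 1000 bases. Consensus words were counted on both strands in the central 500 bases of replicated peaks more than 1000 bases from a gene start. The comparison was with windows 5000 bases to either side that held no peak, by a sign-flip permutation test over peaks (100000 draws, two-sided, Benjamini-Hochberg over 12 words). Words had to match exactly, except that the 14-base RFX word was allowed 2 mismatches. Peaks and neighbouring genes are not independent replicates, so these p-values describe position within these lists, not variation between animals. Mean ± SD over the replicates' own lists (n = 2) is given as the measure of the difference between replicates. Coverage was not scaled between them, so this SD includes the lower total coverage of replicate 2 (18.7 Mb against 30.0 Mb in replicate 1).

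The lists of genes and words, the tests and the alternatives were fixed before the data were examined, as was the rule for named genes. The rule takes the 3 highest and 2 lowest members of each list by coverage, the 20 genes with the highest coverage in the genome, and the genes of the 20 longest domains. Ties were broken alphabetically. The alternatives were other overlap rules, peaks with −log10 q of at least 5, the pooled list, and each replicate's own list, which leaves out the other replicate. Further alternatives were other windows, promoter widths, matchings, joining gaps and word windows. Added only after the data had been seen were 2 alternatives (autosomal genes alone, and words outside soft-masked bases), 16 further gene families and some of the tests of explanations, and the closing section names them. The methods for overlap, genomic distribution, gene lists and words were tested on simulated data. For the gene list test, lists of 15 genes among 21728 were simulated. With coverage raised by 1 percentage point, 16.7% of them had a raw p under 0.05. The share was 50.0% at 2 points and 100% at 4, against 3.0% of null lists. These shares are before adjustment over lists, while the calls below rest on the adjusted p. The share that would pass after adjustment was not simulated and cannot be higher. In the gene list simulation, coverage was shuffled over genes, and every member of a raised list was raised. Families in clusters and the link of coverage to gene length were therefore not simulated. The raised lists were few, so their shares are coarse. With 40% of 5000 peaks planted as shared, the overlap step found 40.8%, and with 30% of 5000 peaks planted at gene starts the promoter share came out at 30.4%.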

Results

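H3K4me1 was mapped in newborn mouse midbrain in 2 biological replicates. The peak lists held 97635 peaks for replicate 1, 66722 for replicate 2, 104359 for both pooled and 46001 in the authors' replicated list. Peaks were short, with a median width of 246 bases in replicate 1, 235 in replicate 2 and 416 in the replicated list. They covered 30.0 Mb, 18.7 Mb and 22.9 Mb, or 1.17%, 0.730% and 0.895% of the assembled chromosomes. The median fold over background, as the authors gave it, was 3.46 in replicate 1 and 3.35 in replicate 2. The recovered heights had a median of 11 reads in replicate 1 and 10 in replicate 2, over commonest backgrounds of 2.357 and 1.984. Heights were thus lower in replicate 2, and 63.8% of its peaks had a q under 0.05 against 89.96% in replicate 1. With heights this low, the absence of a peak is not evidence that the mark was absent.

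The first comparison asked which sites were seen in both replicates. Of the peaks of replicate 1, 31.6% overlapped a peak of replicate 2, and 46.8% of the peaks of replicate 2 overlapped one of replicate 1. Randomly placed peaks overlapped in 1.62% and 2.35%, so sharing was 19.6 and 19.9 times as frequent as by chance (one-sided permutation test, p = 0.0099 for each, the smallest that 100 placements can give). Sharing was more frequent among strong peaks. In replicate 1 it went from 19.3% in the weakest 10% by −log10 p to 65.5% in the strongest, and in replicate 2 from 33.8% to 74.8%. Across 23423 peaks that overlapped one-to-one, the folds of the replicates had a Spearman rho of 0.19, a correlation across peaks, which are not independent replicates. The share of replicate 1 seen in replicate 2 fell to 14.7% when at least 50% of both peaks had to overlap (21.5% in the other direction). Among peaks with −log10 q of at least 5 it was 1.89%, and 45.3% in the other direction. Replicate 1 held 5410 such peaks and replicate 2 only 214, which keeps the share of 1.89% low whatever the agreement.

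All 46001 peaks of the replicated list stood unaltered in the pooled list. Of them, 61.7% overlapped a peak of both replicates by at least 1 base, 36.4% a peak of exactly 1 replicate and 1.88% a peak of neither. The list is therefore not the plain overlap of the deposited replicate lists. Values below rest on it unless the replicates' own lists are named, and a gene with 0% or no peak lacks a peak of the replicated list only.

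Introns and promoters held more peak bases than random placement gave, and intergenic sequence held fewer. Random placement left out only gaps in the assembly, so sequence where reads cannot be placed was not accounted for. Introns held 61.2% of the bases of replicated peaks, against 43.2% for random placement, and promoters 10.5% against 1.72%, a ratio of 6.13. The ratio was 6.65 in 5′ UTRs, 1.79 in coding exons and 2.11 in non-coding exons. Intergenic sequence held 19.7% of peak bases against 50.4% at random, a ratio of 0.391. Each of these 6 classes had an adjusted p of 0.0231 (two-sided permutation test, raw p = 0.0198, the smallest that 100 placements can give), while 3′ UTRs did not pass the test (ratio 0.932, adjusted p = 0.178). The replicates' own peaks held 60.8% ± 0.0209 (SD, n = 2) of their bases in introns, 9.08% ± 0.412 in promoters and 22.4% ± 0.433 in intergenic sequence, so the departures from random were larger than the spread between replicates. The excess in coding exons was lost when promoters were widened to 2500 bases (ratio 1.04, adjusted permutation p = 0.158). The 3′ UTRs fell below random in 5 of 6 alternatives, with ratios of 0.692 to 0.914.

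Around gene starts, the mark lay to both sides, with lower coverage at the start itself than at the maxima beside it. In the replicated list, 3.67% of gene starts were covered at the lowest point within 250 bases of the start. Coverage reached 14.3% at 1150 bases into the gene and 6.43% at 750 bases upstream. Farther out it fell below that of the start, to 1.16% at 4950 bases upstream and 2.19% at 4950 bases into the gene. The replicates' own lists had maxima of 15.1% and 8.90% inside the gene over lowest values of 4.11% and 2.59%, so the downstream maximum was 3.67 and 3.44 times the lowest value, against 3.89 in the replicated list and 7.86 among its peaks with −log10 q of at least 5. A replicated peak covered the start base of 791 of 21728 protein-coding genes (3.64%), lay within 1000 bases of 6471 (29.8%) and within 20000 bases of 12916 (59.4%). The median distance from the centre of a replicated peak to the nearest gene start was 24.4 kb.

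**Figure D1:**
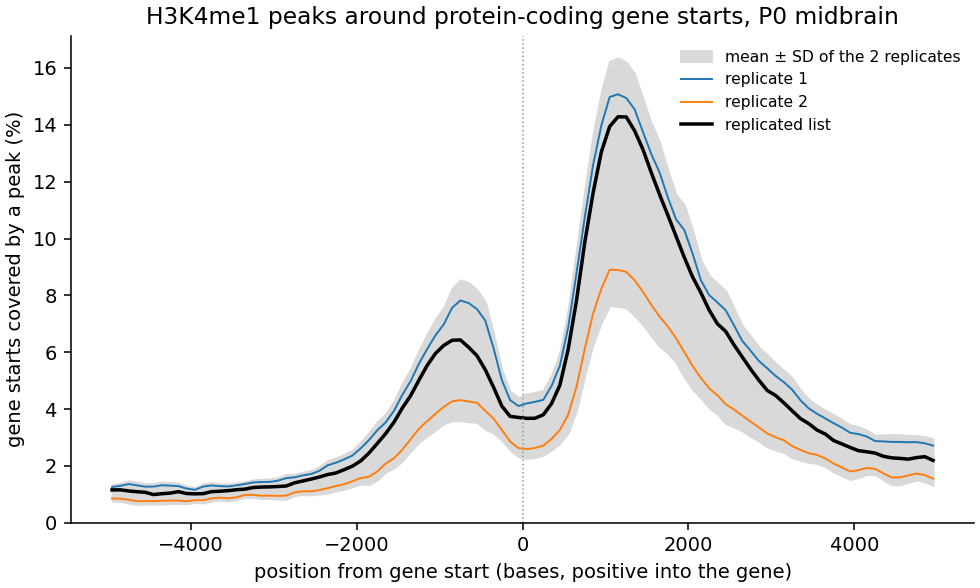
Share of 21728 protein-coding gene starts covered by an H3K4me1 peak (y axis, percent) by position from the gene start in bases (x axis, positive into the gene), for each replicate, their mean ± SD (n = 2) and the replicated list. All lines dip at the start between 2 maxima, rise highest downstream (the replicated list from 3.67% to 14.3%) and fall below the value at the start toward both ends.

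Chromosome X carried far fewer peaks than any autosome. Replicated peaks covered 0.0162% of X, against a median of 0.987% of an autosome, 61.1 times as much, and a range from 0.630% on chromosome 3 to 1.60% on chromosome 11. The replicated list held 79 peaks on X, or 0.0833 per protein-coding gene, where the lowest autosome, chromosome 7, held 1.44 per gene. Each replicate had the same order, with 356 X peaks in replicate 1 and 149 in replicate 2. X coverage was 0.0368% ± 0.0226 (SD, n = 2), and the autosomal median was 24.1 times the X value in replicate 1 and 39.0 times in replicate 2. Among peaks with −log10 q of at least 5, 4 of 8697 lay on X and the ratio was 359.6. How X was treated upstream (filters, control) is not given in the sources used here, and the peak lists do not show it. Of 10 genes on X in the lists of cell types, regions and pathways, 9 had no replicated peak within 20000 bases, and Syn1 had 1.45%.

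**Figure D2:**
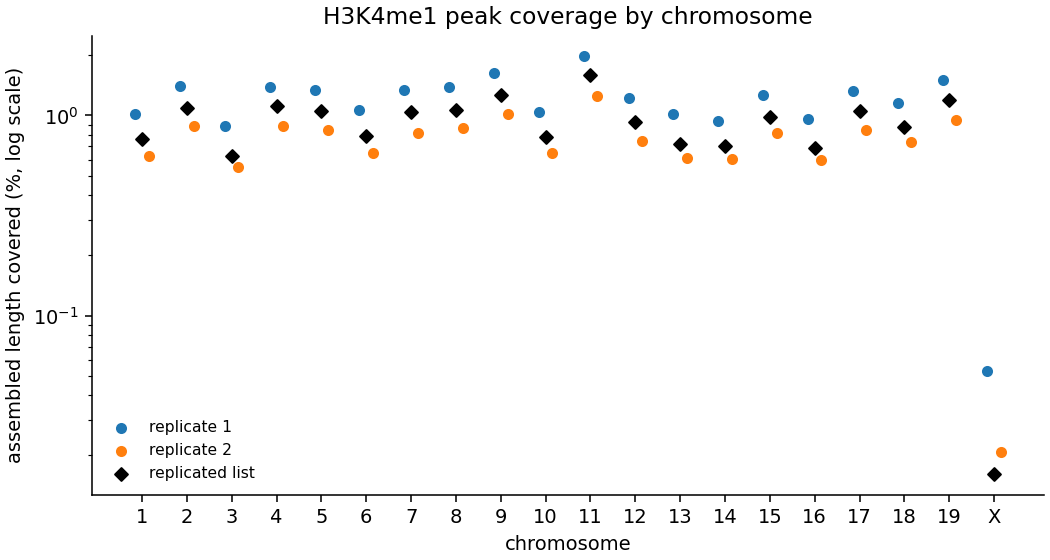
Share of each chromosome's assembled length covered by H3K4me1 peaks (y axis, percent, log scale) by chromosome (x axis), for each replicate and the replicated list. Chromosome X lies apart at 0.0162% in the replicated list, while the autosomes lie between 0.630% and 1.60%.

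The next comparison asked which cell type, region and pathway genes carried the mark. Activity genes, which neurons switch on when stimulated, had the highest coverage of the 24 lists. The median of their 12 members was 6.18% of bases within 20000 of the gene start, against 0.998% for random lists (adjusted p = 0.0096, two-sided permutation test). The medians of the replicates' own lists were 5.31% ± 2.07 (SD, n = 2). None of the 12 genes lacked a replicated peak, and 7 lay above the 90th percentile of all genes. Npas4, a neuronal transcription factor, had 18.5% with 11 peaks, Junb 12.8% and Egr1 8.93%. The lowest members were Bdnf, a neurotrophin, with 2.73% and Jun with 1.2%. Housekeeping genes were also higher, with a median of 4.54% against 0.993% at random (adjusted permutation p = 0.0168) and 4.59% ± 1.72 (SD, n = 2) in the replicates' own lists. Of 14 members, 6 lay above the 90th percentile. The ribosomal protein gene Rps18 had 10.2%, the RNA polymerase II subunit gene Polr2a 9.997% and Ywhaz 9.99%, while 3 members had 0%, Hprt and Pgk1 on X and B2m on chromosome 2. Among peaks with −log10 q of at least 5, the medians were 1.94% against 0.0568% at random for activity genes and 0.787% against 0.0414% for housekeeping genes, and neither passed the test (adjusted permutation p = 0.0816 and 0.432). Housekeeping genes did not pass it with a window of 50000 bases either (3.002% against 1.01%, adjusted permutation p = 0.0643).

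Vomeronasal receptor genes had lower peak coverage than random lists. Of 326 members, 323 had no replicated peak in the window, and the median was 0% against 1.00% (adjusted permutation p = 0.0368). Olfactory receptor genes had no peak at 1100 of 1134 members and did not pass the test (median 0% against 0.741%, adjusted permutation p = 0.126). Their median of 0% already gave the lowest raw p open to them (permutation p = 0.021), so they could not have passed after adjustment. The pool of their random lists held the receptor genes themselves. Without matching on gene length, random lists had 1.05% and the olfactory receptors were lower (adjusted permutation p = 0.0024). Both families lie in clusters whose windows overlap, which makes their p-values too small. How well reads can be placed in these families was not tested, so the result is about called peaks, not absence of the mark. A median cannot fall below 0%, and where many random lists also have 0%, even a family without any peak cannot pass as lower. That was so for the vomeronasal receptors in 4 of 11 alternatives (matching on the number of gene starts nearby, a window of 5000 bases, gene bodies, and −log10 q of at least 5), which therefore say nothing about the call. In the other 7 they were lower (adjusted permutation p of 0.0012 to 0.0048), as were the olfactory receptors in the 8 alternatives where they could be (0.0012 to 0.0024). Hox genes had no peak at 29 of 39 members, against 40.6% of all protein-coding genes, and Hoxd1 was highest with 2.90%. Their median of 0% could not pass as lower. By the mean over members they were lower, with 0.325% against 2.09% (adjusted permutation p = 0.0012). With matching on gene starts their median was 0% against 2.25% without passing the test (adjusted permutation p = 0.122). There too the raw p was the lowest that 0% can give (permutation p = 0.0204), so it could not pass after adjustment. Hox genes lie in clusters as well.

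The neural lists did not pass the test against random lists of the same size and gene lengths, with adjusted p-values of 0.674 to 0.94. Of the 24 lists, only the vomeronasal receptors could have passed as lower by the median after adjustment. By the mean, where all 24 could, the lists that were lower were the vomeronasal receptors, the olfactory receptors and the Hox genes. Among midbrain dopaminergic genes, 1 of 17 lay above the 90th percentile of all genes. Their median was 0.532% in the replicated list, 1.36% in replicate 1, 0.502% in replicate 2 and 2.64% in the pooled list, where it lay above random lists without passing the test. Pitx3, a transcription factor of dopaminergic neurons, had 8.44% and En2 4.78%, while Th, the rate-limiting enzyme of dopamine synthesis, and Ret had 0%. In the replicates' own lists, Th had 0.465% in replicate 1 and 0% in replicate 2, and Ret 0% and 1.01%. Midbrain GABAergic genes (median 1.05%, 14 members, 1.54% ± 0.225 in the replicates' own lists, SD, n = 2) included Slc6a1, the GABA transporter GAT-1, with 27.7%. They also included Zfpm1 with 6.85% and, at the low end, Gad1, a GABA-synthesising enzyme, with 0% (0.475% in replicate 1 and 1.01% in replicate 2). Of 14 midbrain glutamatergic genes (median 1.27%, replicates 1.64% ± 0.492), Tcf7l2 was highest with 8.59% and Ebf1 followed with 4.01%. Tectum and isthmus patterning genes (median 2.02%, replicates 2.15% ± 1.00, 18 members) were led by Fgf17 with 14.8% and Wnt1 with 8.10%, both secreted signals of the midbrain-hindbrain boundary. Pan-neuronal genes (median 2.00%, replicates 2.35% ± 0.884, 19 members) were led by Rbfox3, which encodes the neuronal marker NeuN, with 12.95% and Mapt, which encodes tau, with 7.76%, and they passed the test with a window of 50000 bases (adjusted permutation p = 0.0096). Progenitor and radial glia genes (median 2.08%, replicates 1.99% ± 0.793, 18 members) were led by the Notch target Hes5 with 13.7% and the intermediate filament gene Nes with 6.52%. Axon guidance genes (median 1.51%, replicates 2.21% ± 1.12, 23 members) ranged from Sema3f, a secreted semaphorin, with 20.7% and Efna2 with 11.5% to 10 members with no replicated peak, of which 9 had a peak in a replicate's own list. In the serotonergic list (median 0.637%, replicates 1.33% ± 0.0946, 8 members), the transcription factor gene Fev had 7.68% and the serotonin transporter gene Slc6a4 0% (0% in replicate 1 and 1.16% in replicate 2). Over the lists of cell types, regions and pathways, 71 of 111 entries without a replicated peak had a peak in a replicate's own list.

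Markers of other cell types and regions did not pass the test either, with adjusted p-values of 0.737 to 0.94. Astrocyte genes had a median of 1.75%, led by the glutamate transporter gene Slc1a2 with 8.55%. Oligodendrocyte lineage genes had a median of 1.22%, led by Sox8 with 8.33%, and Plp1, on X, had 0%. Microglia genes had a median of 0.275%, led by the complement gene C1qa with 5.63%, and endothelium and pericyte genes 1.03%, led by Foxf2 with 4.58%. Telencephalon genes had a median of 1.92%, led by Bcl11b with 5.19%, and hindbrain genes 0%, led by Egr2 with 8.18%. The medians were 0% for liver, erythroid and germ cell genes, 0.83% for muscle genes and 0.435% for T cell genes. In the replicates' own lists, the medians of these 11 lists ranged from 0.154% ± 0.218 (SD, n = 2) for liver to 1.95% ± 0.399 for astrocytes. The muscle gene Myh7 had 9.43%, more than any of the 17 dopaminergic or the 14 glutamatergic genes.

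**Figure D3:**
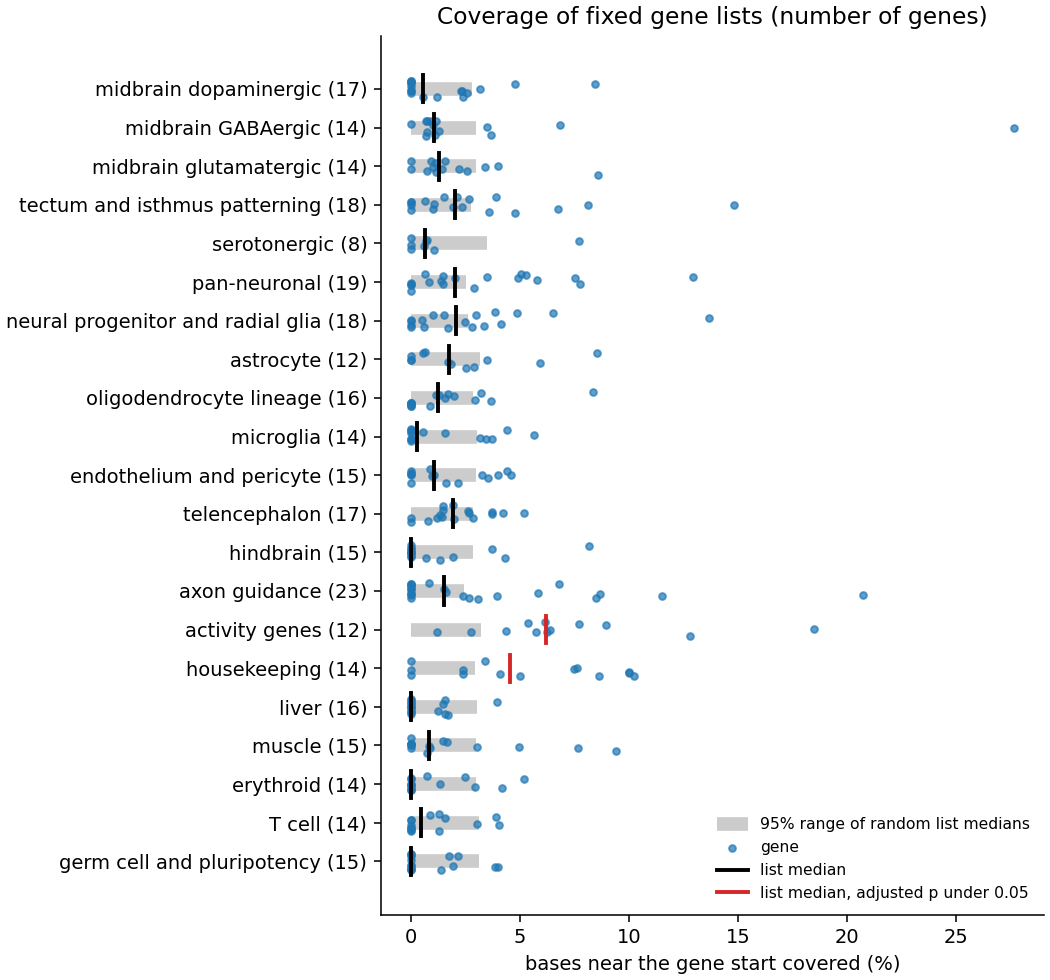
Share of bases within 20000 of the gene start covered by replicated H3K4me1 peaks (x axis, percent) for each member of 21 gene lists (y axis, number of genes in brackets). Points are genes, vertical bars list medians and grey bars the 95% range of the medians of random lists. The medians of activity genes (6.18%) and housekeeping genes (4.54%) lie beyond that range.

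Across the genome, the median gene had 1.05% of its window covered and the 90th percentile was 5.81%. The highest coverage was at Bcl9l, a Wnt pathway co-activator gene, with 35% (chromosome 9, 44482825 to 44511896, GRCm38). It held 17 replicated peaks, and coverage by the replicates' own lists was 23.5% ± 0.189 (SD, n = 2). Tle3, a Groucho-family co-repressor gene, had 28.8%, Ccdc85c 28.7% and Rgs8, a regulator of G protein signalling, 27.7%. The clustered protocadherin genes Pcdhgc5 (27.9%), Pcdhgc4 (27.1%) and Pcdhgc3 (24.7%) share overlapping windows, so they are 1 region of chromosome 18 rather than 3 independent genes. Genes with neuronal roles among the 20 highest included Slc6a1 (27.7%), the ephrin gene Efnb3 (27.1%), the synaptic adhesion gene Nrxn2 (26.5%) and the kinase gene Brsk2 (25.8%). Chromatin and transcription genes included Bahcc1 (27.4%), Zmiz1 (26.9%), the co-repressor gene Ncor2 (25.8%), Cxxc5 (25.01%) and the Polycomb gene Cbx8 (23.3%). The others were Sdc3 (25.5%), Mfhas1 (25.5%), Pipox (23.9%) and Wdr24 (23.5%). The spread between replicates was larger for some of these genes, as at Nrxn2 with 20.4% ± 9.44 (SD, n = 2) and Brsk2 with 18.5% ± 10.4. At both genes replicate 1 had the higher coverage.

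Joined across gaps of up to 1000 bases, the replicated peaks formed 34603 domains with a median length of 488 bases, of which 144 reached 5 kb. The longest, 16.1 kb, lay at Zmynd8, which encodes a chromatin reader, at 165873484 to 165889553 of chromosome 2. Introns made up 72.3% of it, and peaks of replicates 1 and 2 covered 60.1% and 60.6% of it. The next were a 13.4 kb intergenic domain of chromosome 12, from 86798923 to 86812308, whose nearest gene start is that of Lrrc74a, and intronic domains at Tcf20 (12.7 kb) and Tspan5 (11.2 kb). A domain of 10.96 kb in the protocadherin gamma cluster, assigned to the read-through record Gm37013, had coding exon as its main class, with 32.7% of its bases, and held a gene start. The domain of Slc6a1 ran for 10.5 kb within introns, from 114284048 to 114294519 of chromosome 6. The remaining domains of the 20 longest, from 10.7 kb down to 8.07 kb, lay at Mfhas1, Ahdc1, Ncor2, Gm20388, Psap, Cacna1g, Irf2bp2, Zmiz1, Pbx1, Igsf9b, Map4k4, Basp1, Ildr2 and Med13l. Gm20388 is another record that spans neighbouring genes, and Irf2bp2 is only the nearest start to an intergenic domain. Introns were the main class in 17 of the 20 domains, and only the domains at Gm37013 and Mfhas1 held a protein-coding gene start. All 20 domains held peaks of both replicates. The ranking depended on the settings: of the 20 domains, 3 recurred among the 20 longest at a gap of 0, 6 at 3000 bases, 5 among peaks with −log10 q of at least 5 and 8 to 10 in the pooled list or a replicate's own list. The longest domain then lay at Fads2 (gap of 0, 4.98 kb), Tcf20 (3000 bases, 31.9 kb, and pooled list, 21.2 kb), Thra (−log10 q of at least 5, 7.51 kb) and Add2 (replicate 1, 13.8 kb), and stayed at Zmynd8 in replicate 2.

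**Figure D4:**
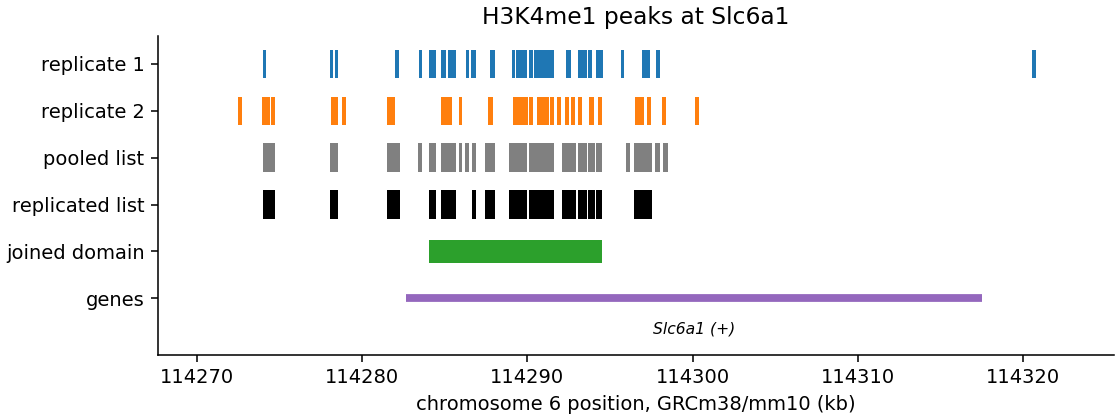
Peaks of each replicate, the pooled list and the replicated list at Slc6a1 (x axis, position on chromosome 6 in kb, GRCm38/mm10), with the joined domain and protein-coding genes, drawn to scale. The 10.5 kb domain starts downstream of the gene start, within the gene.

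The last comparison asked which binding words were more frequent in distal peaks, which lay more than 1000 bases from a gene start. In 34947 distal peaks, the RFX word, a palindrome bound by RFX factors, occurred 0.0541 times per kb against 0.0079 in the flanks, a ratio of 6.86. Words of MEF2 factors (ratio 1.39), SOX factors (1.15) and basic helix-loop-helix E-boxes (1.14) were also more frequent (adjusted p = 2.4e-05 for each of these 4, two-sided sign-flip permutation test, raw p = 1e-05, the smallest that the draws can give). The excess of RFX words was 0.0462 ± 0.00182 (SE) per kb and that of E-boxes 0.239 ± 0.0128 per kb. With flanks matched on C+G content these words still passed the test, with an excess of 0.0453 ± 0.00284 per kb for RFX and 0.132 ± 0.0222 for E-boxes, and ratios of 1.94 for MEF2, 1.17 for SOX and 1.08 for E-boxes. The homeobox word was less frequent (ratio 0.895, adjusted permutation p = 2.4e-05), but more frequent where flanks were matched on C+G content (ratio 1.23). Peaks had 49.1% C+G and flanks 45.6%. Matching on C+G kept 15451 of the 34947 peaks, each set against a single flank, so calls lost, gained or reversed there also rest on fewer peaks. The CTCF core word was more frequent (ratio 1.29, adjusted permutation p = 0.0326) and the GATA word less frequent (ratio 0.943, adjusted p = 0.0364), and both calls were lost after C+G matching (ratios 1.07 and 1.07). The CTCF ratio turned below 1 in the central 200 bases (0.819) and among peaks with −log10 q of at least 5 (0.719), without passing the test in either. Words of nuclear factor I, forkhead, AP-1, PU.1 and HNF4 did not pass the test (adjusted p of 0.102 to 0.701). The forkhead and PU.1 words passed it after C+G matching, with ratios of 1.204 and 0.821.

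**Figure D5:**
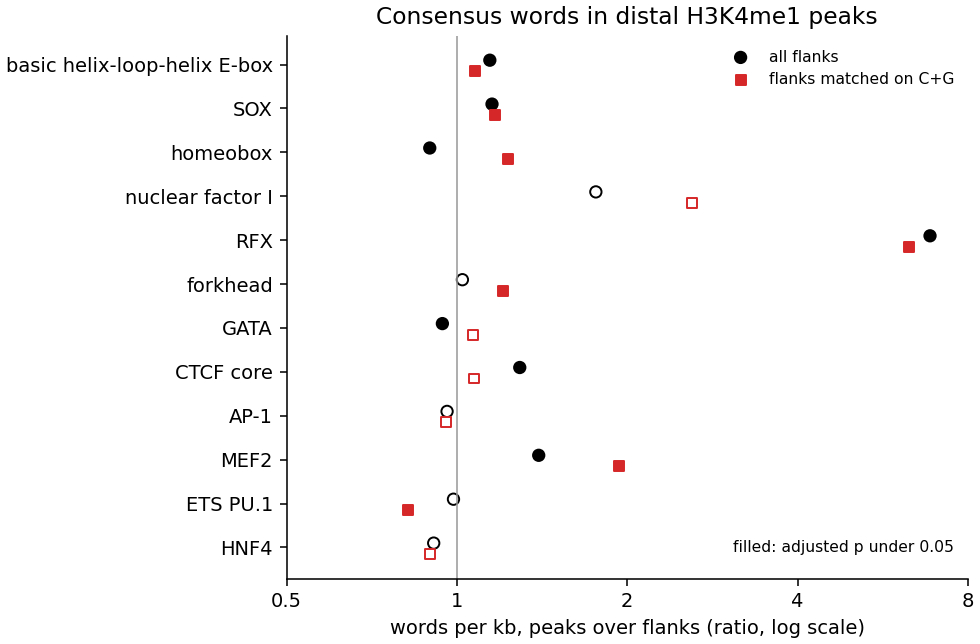
Frequency of 12 consensus words in distal H3K4me1 peaks over that in flanking windows (x axis, ratio, log scale) by factor family (y axis). Black circles use all flanks, red squares flanks matched on C+G content, and filled symbols have an adjusted p under 0.05. RFX stands apart at 6.86, and homeobox lies on opposite sides of 1 by the choice of flanks.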

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

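The alternatives of autosomal genes only and of words outside soft-masked bases were chosen after the data had been seen, and the others before. Of 424 alternative values, 310 kept their direction and side of the threshold or moved little (within 1 replicate SD, or 1.5 times for counts), 40 were values that passed no test and lay on the other side of no difference, 14 lost the call (4 of them values of the vomeronasal receptors where no lower call was possible), 23 gained one, 33 moved and 4 reversed. The cause was not tested for any change below, except that a stricter q or a larger overlap keeps fewer peaks by construction.

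The share of replicate 1 seen in replicate 2 was 19.5% when at least 50% of the peak had to be covered, 14.7% for 50% of both peaks, 1.89% for −log10 q of at least 5 and 36.9% for equal numbers of peaks. The share of replicate 2 seen in replicate 1 was 34.8%, 21.5%, 45.3% and 38.6% in the same order. The rho of the folds was 0.263 for 50% of both peaks. The coding exon ratio was 1.04 with promoters of 2500 bases. The 3′ UTR ratio was 0.875 for pooled peaks, 0.692 with promoters of 2500 bases, 0.865 for peak centres and 0.883 to 0.914 with a replicate left out. The downstream maximum over the lowest value was 3.22 for pooled peaks, 7.86 for −log10 q of at least 5 and 3.44 to 3.67 with a replicate left out. The autosomal median over X was 36.6 for pooled peaks, 359.6 for −log10 q of at least 5 and 24.1 to 39.0 with a replicate left out. The longest domain, which lay at another gene than Zmynd8 except without replicate 1, was 21.2 kb for pooled peaks, 7.51 kb for −log10 q of at least 5, 4.98 kb at a gap of 0, 31.9 kb at a gap of 3000 bases and 13.8 to 15.4 kb with a replicate left out.

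With −log10 q of at least 5, the lists higher than random numbered 0 and the lists lower 0. There and with a window of 5000 bases, no list could have been lower, so these counts of 0 lower lists were fixed by the setting. Over gene bodies, 2 of 24 could reach a raw p under 0.05 as lower, neither of them a receptor family. The count of 0 lower lists there says nothing about the receptor families. The lists lower numbered 2 for pooled peaks, 2 to 2 with a replicate left out, 0 with a window of 5000 bases, 2 with 50000 bases, 0 over gene bodies, 2 without matching, 3 by the mean and 2 with autosomal genes only. The homeobox ratio reversed to 1.23 after C+G matching. The nuclear factor I ratio passed the test at 2.23 for pooled peaks and 1.83 to 2.83 with a replicate left out. The forkhead ratio passed it at 1.06 for pooled peaks, 1.05 to 1.06 with a replicate left out and 1.204 after C+G matching, and the PU.1 ratio at 0.821 after C+G matching. The GATA ratio lost the call at 0.983 for pooled peaks, 0.892 for −log10 q of at least 5, 0.976 to 0.992 with a replicate left out and 0.963 in the central 200 bases. After C+G matching it changed direction to 1.07 without passing the test. The CTCF ratio changed direction to 0.719 for −log10 q of at least 5 and 0.819 in the central 200 bases, without passing the test in either. It lost the call at 1.07 after C+G matching. Among the reversals, only that of the homeobox ratio passed the test on its new side. No paired analysis was possible because the series holds a single group.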

Other observations

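The 16 further gene families, their tests without genes already named, the C+G and soft-masked tests of the RFX word, the test of the covered parts of X, the test of X peaks of the usual height and the rules that set aside the copy number and background tests were chosen after the data had been seen, C+G matching itself having been planned as an alternative. The bounds of the soft-masked test and of the tests not named here were written before their own results were seen, though the patterns they bear on had been. Among these families, 4 were higher than random lists of the same size and gene lengths (two-sided permutation test, adjusted over the 16 families). Ephrins and their Eph receptors had a median coverage of 4.45% against 1.19% at random (adjusted permutation p = 0.00107; 22 genes), with Efnb3 at 27.1%, Efna2 at 11.5% and Ephb2 at 11.5%. Semaphorins, which guide axons, had 3.58% against 1.23% (adjusted permutation p = 0.0088; 20 genes), with Sema3f at 20.7% and Sema4b at 13.9%. Both families also passed the test against lists matched on the number of gene starts nearby (adjusted permutation p = 0.0032 and 0.0072). They were chosen after Sema3f and Efna2 had been seen to lead the axon guidance list and Efnb3 to be among the 20 highest genes, while that list itself did not pass the test (median 1.51%, adjusted permutation p = 0.892), with Sema3a, Sema3c, Efna5, Epha5 and Epha7 at 0%. Without the members of the fixed lists and of the 20 highest genes, ephrins and Eph receptors had 5.11% against 1.22% (15 genes, adjusted permutation p = 0.00213) and semaphorins 4.04% against 1.24% (17 genes, adjusted p = 0.0096). This left out 7 and 3 genes, among them the members at 0% just named. Leaving those out raises the medians, so these values do not remove the effect of the choice of families. Cytosolic ribosomal protein genes had 2.57% against 0.368% (adjusted permutation p = 0.00107; 77 genes), with Rpl18 at 20.0%, and passed it with that matching at adjusted p = 0.0469, where random lists had 1.45%. Histone cluster genes had 3.36% against 0.297% (adjusted permutation p = 0.00107) and did not pass it with that matching (random lists 2.65%, adjusted p = 0.364), and their 67 genes lie in 9 separate windows.

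The other 12 families did not pass the test. Potassium channel genes had 1.83% (adjusted permutation p = 0.0696), led by Kcnq2 at 14.4%, and SOX factors 3.05% (adjusted p = 0.0656), led by Sox12 at 8.95%. Both passed it with matching on gene starts (adjusted permutation p = 0.0072 and 0.0384). Clustered protocadherins had no replicated peak at 51 of 56 genes, while Pcdhgc3, Pcdhgc4 and Pcdhgc5 were among the 20 genes with the highest coverage. Their median of 0% did not pass the test (adjusted permutation p = 0.22) and was lower with matching on gene starts (adjusted p = 0.0072), with 7 separate windows. The medians were 1.77% for ionotropic glutamate receptors (adjusted permutation p = 0.4), 1.34% for forkhead factors (0.4), 3.43% for Hes and Hey genes (0.13) and 2.20% for chromodomain and lysine demethylase genes (0.13). They were 0% for GABA-A receptor subunits (adjusted permutation p = 0.243; 13 of 19 genes without a peak), Zfp9xx zinc finger genes (0.0672), keratins (0.638), defensins (1) and cytochrome P450 genes (0.0656). With a median of 0%, the protocadherins (without matching on gene starts), GABA-A receptor subunits, keratins and defensins could not have passed as lower. Nor could the Zfp9xx and cytochrome P450 genes after adjustment, since their raw p was already the lowest that 0% can give (permutation p = 0.0294 and 0.0246).

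Chromosome X held few peaks. Fewer genes on X cannot be the whole cause, since X held 0.0579 times as many peaks per gene as the lowest autosome. Nor can whole 5 Mb bins of X left out with the rest at the autosomal level, since the bins with a pooled peak were covered at 0.0374 of the autosomal median. Smaller parts left out inside such bins would not show in this test. A part of X left out of the lists or other upstream treatment of X stays open (72.7% of its 5 Mb bins held a peak, between the bounds set beforehand), as does a higher background on X: called peaks gave a ratio of 1.00 at most, but their medians lie at the lowest background of the lists, and sites without a peak give none. Of the X peaks of replicate 1, 3.09% lay at or above the autosomal 90th percentile of height (exact 95% interval 1.55 to 5.46). Of its autosomal peaks, 13.02% did (Fisher's exact test, p = 1.28e-10). The called X peaks were thus lower than the autosomal ones. That cannot decide on a mere lack of sites, since weak false calls among the few X peaks would lower the share as well. A lower copy number of X in these pools of both sexes may contribute and cannot be told apart: X heights were 0.579 and 0.6 times the autosomal ones at equal rank per Mb, inside the range set beforehand and below the 0.75 of an equal mix of the sexes, but autosomal peaks taken evenly from all heights would give 0.647 and 0.667.

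Most peaks of replicate 1 were not seen in replicate 2. Weak peaks missed in the replicate with lower heights may account for part of this. The share seen was 3.40 times higher in the strongest 10% than in the weakest 10% by −log10 p. That rise cannot single out this explanation, since the share of replicate 2 seen in replicate 1 rose with strength too, from 33.8% to 74.8%. No biological explanation was tested for this pattern, as the design holds a single group.

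RFX words were 6.86 times as frequent in distal peaks as in flanks. The ratio was 6.30 with matching on C+G content and 6.08 outside soft-masked bases, and 0 of 100 other palindromes of the same bases gave as high a ratio (highest 3.33), which argues against these as the whole cause. Most of these palindromes held the base pair step CG, unlike the RFX word, and many of them had few matches. The highest ratio rested on 5 matches in peaks, and without CG the highest was 1.81. Whether peaks with RFX words lie by cilia genes, where RFX factors are known to act, stays open, since 1 of 46 cilia genes and 499 of 21682 others had one nearby (odds ratio 0.943, 95% interval 0.0233 to 5.56; Fisher's exact test, p = 1). Binding by RFX factors at these sites may remain as a hypothesis, and no binding was measured here.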
